A study of Homo sapiens and Oryza sativa Indica Group and Arabidopsis thaliana with 12 samples.

How the data were processed

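The series holds 12 samples in 7 groups, of which 10 are TaDRIM-Seq libraries and 2 are CUT&Tag libraries. Per the labels, TaDRIM-Seq tags the DNA around an antibody target with a protein G-Tn5 transposase and joins nearby RNA to it by proximity ligation in nuclei, and CUT&Tag profiles the DNA of the target alone. Only 1 processed table was analysed here. It is the output of a read counter, and it lists gene models with 1 column of whole-number counts.

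That count column was not used in any step. It is named for a single numbered alignment file in a folder called RTTag, a name that no sample carries, and neither this name nor that of the table matches the labels of any of the 12 samples. The table's name gives RT_Tag, K562 cells and the H3K4me3 antibody. The 4 K562 samples are instead labelled as TaDRIM-Seq libraries in 2 fixation groups, and nothing ties the column to either. The number of columns left out for this reason is 1. No depth, expression level, fold change or test between groups is therefore reported, and the planned edgeR comparisons (K562 fixed for 5 min against 30 s, and K562 against 293T), the RNA make-up of each library and the replicate agreement were not run. The processed values of the Arabidopsis and rice samples were not analysed here.

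Per the file headers, the authors ran featureCounts 2.0.0 in paired-end mode on 1 alignment file with strand option 2. That setting is for reversely stranded libraries, and it covers genes on both strands. Exons were summed by gene identifier with GENCODE release 44 on hg38. The header records no option for multi-mapping reads and none for reads that overlap several genes. The alignment file's name carries the mark q30, whose meaning is not given in the sources used here. Per the submitters' processing notes, Trimmomatic, BWA, HISAT2 and Bowtie2 were used, and which of them made this alignment is not given in the sources used here. The deposited length column holds the exonic length of each model in base pairs.

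The gene identifier, chromosome, exon starts and ends, strand and length were taken from the deposited table with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Exons of a gene were merged into blocks. The merged length equalled the deposited length for every one of the 62700 models, with 0 differences. The exonic share is the merged exonic length as a percent of the span from the first to the last exonic base. Exonic bases were called shared when they also lay in an exon of another gene, from 1 base upward, on the same strand or on the opposite strand. The overlap code was tested on simulated data against a count of single bases and gave 0 mismatches in 1640 comparisons.

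The table gives identifiers and no symbols, and the name table used here pairs none of these identifiers with a symbol. Names were therefore taken by position from RefSeq genes of GRCh38.p14, the same primary build. A name was used where the RefSeq span and the model's span each overlapped by at least 80% and where the match was 1 to 1. The name table has no strand, so strand was not checked. The rule compares spans, and the span is also the denominator of the exonic share. List medians therefore describe matched members only, and whether unmatched members differ was not tested. This named 33987 models, or 54.2% of the total, and 150 of the 210 members of 14 gene lists fixed before the data were examined. The rule that had been fixed for naming genes ranks them by expression or by a test and could not be applied, so the genes named below were chosen after their values were seen, mostly as the extremes of each list. All alternatives in the closing section were also chosen after the table was seen.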

Results

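The series was built around TaDRIM-Seq, an assay of RNA associated with chromatin at targeted DNA elements and of contacts between RNAs in nuclei. Its human part comprised 6 libraries made with an antibody to H3K4me3, a histone mark of active promoters. K562, an erythroleukaemia cell line, was fixed in 1% formaldehyde for 30 s in 2 libraries and for 5 min in 2 libraries, according to the sample titles. The growth protocol shared by the samples gives 10 min instead, and this conflict was not resolved here. A further 2 libraries came from 293T, a line derived from human embryonic kidney. The plant part comprised 2 H3K4me3 libraries from Arabidopsis young leaves, 2 histone H3 libraries from rice young leaves and 2 CUT&Tag libraries from rice mature leaves. One of the rice CUT&Tag libraries was titled for H3K9ac and the other for H3K27me3, although a further label of the first also names H3K27me3. The design implies comparisons between the fixation times and between the human lines. Neither comparison could be made here, because the only column of counts in the table used here matched no sample's labels and was left out. The depth of the libraries is therefore unknown here, and no RNA level is reported.

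What could be described was which parts of genes this 1 counting run, tied to no sample, was set up to measure. In it, counting was restricted to exons and was strand-specific, for genes on both strands. Whether any TaDRIM-Seq library was counted in this way is not known here. The values below are properties of the GENCODE models on hg38 that the table lists. They cover every listed model, so they carry no sampling error and no replicates, and they say nothing about RNA in the cells.

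In models whose exons formed more than 1 block, exons made up a small part of the gene span. Of the 62700 models on 25 chromosomes, 38884 had more than 1 exon block, and in these the median exonic share of the gene span was 15.6%, with quartiles of 6.38% and 37.0%. In 976 of them the exonic share was under 1%. The remaining 23816 models had 1 exon block. A block joins the exons of all transcripts of a gene, so a single block does not mean that the gene has no intron. RPL23, SNHG1, GADD45B and TUG1 were single blocks at 100%. With single-block models included, the median exonic share was 45.7%. Summed over all models, exons covered 8.07% of the summed spans. Among models named from RefSeq by position, the median exonic share was 18.0% in 16436 protein-coding genes and 14.7% in 4885 lncRNA genes, and 100% in 714 snoRNA, 77 snRNA and 1766 miRNA genes.

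The fixed gene lists spanned this whole range. Very long protein-coding genes had the lowest list median, 0.979%, over all 16 members. The span is the denominator of the share, so a low median largely follows from listing genes by their length. IMMP2L, a mitochondrial inner membrane peptidase subunit, was at 0.441% (chromosome 7, 110662644 to 111562517), FHIT at 0.497% (chromosome 3, 59747277 to 61251459) and PTPRD, a receptor tyrosine phosphatase, at 0.499% (chromosome 9, 8314246 to 10613002). FTO, an RNA demethylase, had the highest share of that list, 4.68%. The list for the BCR-ABL locus holds 5 genes, of which BCR and ABL1 form the fusion carried by K562. The list median was 13.5%, the value of PRDM12. BCR was at 8.84% (chromosome 22, 23179704 to 23318037) and ABL1 at 4.00% (chromosome 9, 130713043 to 130887675).

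Erythroid genes, the main lineage list for K562, had a median exonic share of 25.9% over 21 of 28 members. The matched globin genes lay at the top of the list, with HBA1 at 99.1% (chromosome 16, 176680 to 177522), HBA2 at 99.0% and HBG1, a fetal globin gene, at 92.3% (chromosome 11, 5248269 to 5249857). The globin genes HBG2, HBE1, HBZ, HBB and HBM were among the unmatched members. The erythroid transcription factor genes varied, with KLF1 at 58.0%, TAL1 at 35.8%, NFE2 at 26.5%, BCL11A at 23.6% and GATA1 at 20.0%. The regulator genes LMO2 and ZFPM1 were lower, at 8.64% and 7.36%. ANK1, which encodes the erythrocyte membrane protein ankyrin, was lowest at 4.52%. The 293T list had a median of 34.9% over 12 of 14 members, from 2.36% for EYA1 to 100% for SOX4. The myeloid and megakaryocyte list had a median of 40.0% over 7 of 10 members.

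The medians of the remaining lists ran from 21.9% to 100%. All 8 matched replication-dependent histone genes of 15 listed were single blocks with a share of 100%, which a single block has by definition. The same held for the 14 matched genes of 16 in the spliceosomal and 7SK snRNA list and for the 11 matched of 14 other small structured RNA genes. RN7SK, the gene of 7SK RNA, was among the unmatched members. Immediate-early and stress genes had a median of 82.0% over 13 of 16 members, with FOS at 93.6% and EGR1 at 82.0% but ATF3 at 7.21%. AHSP, a haemoglobin-stabilising protein gene of the erythroid list, was at 58.2% over a span of 904 bp. Cytoplasmic ribosomal protein genes had a median of 66.2% over 12 of 16 members, housekeeping genes 41.0% over 6 of 13, and cell cycle genes 21.9% over all 15. The list labelled nuclear lncRNA had a median of 91.5% over 10 of 19 members. The label was not checked, and not every member need be mainly nuclear. The unmatched members included MALAT1, MEG3, PVT1 and GAS5. Over all 4885 named lncRNA genes the median was 14.7%, so the matched members do not stand for lncRNA genes at large. NEAT1, the scaffold RNA of paraspeckles, was at 100% (chromosome 11, 65422774 to 65445540), KCNQ1OT1, an imprinted antisense transcript, at 90.2%, and DLEU2 at 7.57%. None of the 13 mitochondrial-encoded genes was matched by name.

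**Figure D1:**
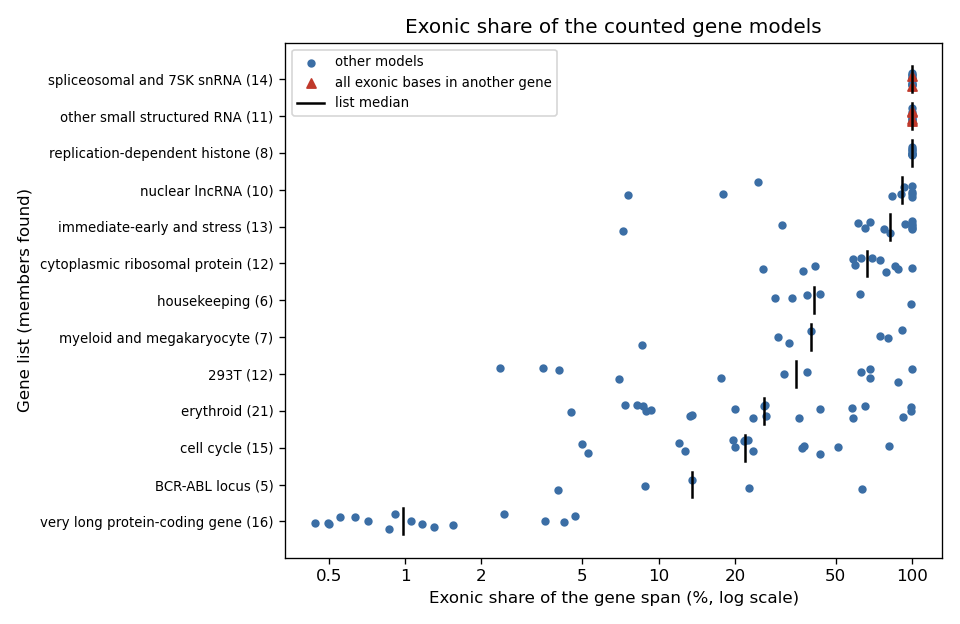
Each point is a gene model, placed by its exonic share of the gene span in percent on a log axis, in rows by gene list with the number of members found. Black bars are list medians, from 0.979% for very long protein-coding genes to 100% for the small RNA and histone lists, and red triangles mark the 6 models whose exonic bases all lie in an exon of another gene on the same strand.

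Some exonic bases belonged to more than 1 gene on the same strand, so that a read lying there overlapped several genes. This held for at least 1 base in 8479 models, or 13.5%, and for every exonic base in 1738 models, or 2.77%. Shared bases were 4.24% of all exonic bases. Of the 1738 wholly shared models, 733 were named by position, and the classes below hold only named models. A name needed a 1 to 1 match of spans, so models with nearly the same span could go unnamed. The shares by class may therefore depend on the naming rule, which was not tested. Among models named from RefSeq, every exonic base was shared in 172 of 714 snoRNA genes (24.1%), in 274 of 1766 miRNA genes (15.5%) and in 6 of 77 snRNA genes (7.79%), compared with 72 of 16436 protein-coding genes (0.438%) and 16 of 4885 lncRNA genes (0.328%). Transcribed pseudogenes lay between, at 27 of 579 (4.66%). The order differed for sharing of at least 1 base, which was found in 55.8% of transcribed pseudogenes, 29.6% of snoRNA, 20.4% of miRNA, 14.1% of protein-coding, 9.09% of snRNA and 8.21% of lncRNA genes. Other pseudogenes, 8942 models, were lower at 4.97%, with 1.74% wholly shared, and the immunoglobulin and T-cell receptor J segments, V segments and V segment pseudogenes shared bases in 2.17%, 1.01% and 0%. Classes of fewer than 50 named models were left out. At least 1 exonic base was also covered by an exon of a gene on the opposite strand in 14656 models, or 23.4%. For a read pair lying wholly within such bases, the strand tells the genes apart.

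Among the 150 matched list genes, 34 shared bases on the same strand and 6 were wholly shared, all of them small structured RNAs. RNU2-2, a U2 spliceosomal snRNA gene (chromosome 11, 62841619 to 62841809), had all 191 bases inside an exon of WDR74. SNORD118, the gene of the U8 snoRNA (chromosome 17, 8173454 to 8173587), had all 134 bases inside an exon of TMEM107. All 150 bases of RNU12, the gene of the U12 snRNA, and all 333 bases of RPPH1, the RNA of RNase P, lay in exons of models that position did not name. The same was true of the 99 bases of VTRNA1-1, a vault RNA gene. RN7SL2, a gene of the signal recognition particle RNA, had all 300 bases in an exon of LOC105378179. By contrast RNU1-1, RNU2-1, RNU4-1, RNU4-2, RNU6-1, RN7SL1 and RMRP shared 0 bases on the same strand. Sharing is by position only. Similarity of sequence between genes was not measured, so 0 shared bases does not mean that reads can be told apart. Of the part-shared genes, SCARNA10, a small Cajal body RNA gene, was highest at 75.2% of its exonic bases. PF4, a platelet chemokine gene, followed at 52.1%, ZBTB20 at 43.0%, HSPA1B at 36.6%, PPBP at 34.7% and RPS2 at 25.9%. SNHG1, a snoRNA host gene, was at 15.4%, and HBG1 at 14.9%.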

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

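No alternative planned before the data were examined could be run, because each needs counts that can be tied to a sample. No paired analysis was possible because the table carries no column for any of the groups that share replicate numbers. The alternatives given here were all chosen after the table was seen. The number of models sharing exonic bases on the same strand, 8479, became 20625 with strand ignored and 4082 among the models named by position. The number wholly shared, 1738, became 2633 with strand ignored and 733 among the named models. As shares, these were 12.01% of the named against 13.5% of all models, and 2.16% against 2.77%, so most of each fall came from the smaller set. The cause of the rest was not tested. The median exonic share, 15.6% in models with over 1 exon block, became 45.7% when models of 1 block were included and 16.4% among the named models. A floor of 50 shared bases gave 8061 sharing models, and a limit of 90% of exonic bases gave 2310 nearly wholly shared models, both within 1.5 times the reported counts. Requiring 50%, 90% or 95% overlap for a name matched between 140 and 158 list genes.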
